A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

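Poly(A) RNA was measured in 8 samples, 4 of WT and 4 of mcd1-1, with replicates A to D in each group as the labels name them. The cells started at an optical density of 0.2 and grew for 2 generations at 31 °C, and the libraries were made with a NEBNext Ultra kit and sequenced on a HiSeq X, per the labels. The deposited values are raw counts of reads per gene, which the authors had not normalised. The submitters' processing notes name bcl2fastq 2.9, Trim Galore 0.4.3, STAR 2.5.3a, Picard and featureCounts 1.6.0 and the genome build R64, with no settings. The strand setting and the treatment of reads shared by several places are not given in the sources used here.

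The table holds 6596 gene models, and 4 lines of it were empty as received. Coordinates in the table were compared with the annotation of the RefSeq genome of budding yeast. Of the models, 5914 matched a RefSeq locus tag, 5885 of them with the same start and end, 29 matched with other coordinates, and 682 had no match. Spans were a multiple of 3 in 97.0% of models, and 1241 models overlapped another. A near-identical copy, meaning at least 90% identity over at least 100 bp to another model by blastn 2.17.0, was found for 398 models, 20 of them among the named genes, so that shared reads leave the values of these and of overlapping models uncertain.

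The totals were 22331070 to 58506447 counts per library. The most abundant gene, TEF1, took 1.60 to 2.18% of counts in WT and 1.02 to 1.55% in mcd1-1. A count of 0 allows up to 3 counts, or 0.051 to 0.134 CPM per library, and intervals and floors cover counting error only. Replicates of a group differed by more than sampling noise in each pair. Chi-square per degree of freedom was 11.9 to 101 within A and B or within C and D, and 315 to 541 across them. Each library was counted as 1 replicate, though such values do not show that the libraries are independent.

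Gene models were kept by edgeR's filterByExpr, which left 6558, and scaled by TMM, whose factors were 0.879 to 0.902 in WT and 1.09 to 1.21 in mcd1-1. The contrast of mcd1-1 with WT was tested in edgeR 4.0.16 by the quasi-likelihood F test, 2-sided, with group as the only term and a common biological coefficient of variation of 0.253. P-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05, and a fold threshold of 2 was used for the second count. CPM values are TMM-scaled, and standard errors of log2 fold changes follow from the F statistic. Lists were tested with camera in limma 3.58.1 against the genes outside the list, with a preset correlation of 0.01 and adjustment within each family of 36 gene lists, 3 positional lists and 16 chromosomes. A list needed at least 3 tested members. The 36 gene lists held 1055 matched members from general knowledge of yeast biology, and 1 member, the mating-type gene MATA1, matched no model. Chromosome medians per library were compared by an exact permutation test.

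Named genes followed a rule with 4 parts. The first took MCD1 and the other cohesin genes. The second took the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 10 CPM and all 4 mcd1-1 libraries on the same side of all 4 WT libraries, which 2191 genes met. The third took the 4 members of each gene list or positional list with the smallest p, and the last took the strain marker and mating-type lists. The neighbours of MCD1, taken by position, and the genes in the last part of the closing section were chosen after the data were seen. The groups, the test, the lists, the rule for named genes and the settings listed first below were fixed before the data were examined.

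The other settings fixed in this way were DESeq2 1.42.0, RLE, upper-quartile and library-size scaling, TMM without ribosomal protein genes, no low-count filter, a filter of 10 CPM in 4 libraries, limma-voom, robust quasi-likelihood, the replicate letter as a block, leaving out each library, an estimated correlation for the lists, fry, camera on voom values, 10 or 30 kb around centromeres, and 15 or 50 kb from chromosome ends. Added after seeing the data were libraries A and B against C and D as a block, each of these sets alone, the replicate block with a GC and length correction, lists with the abundance trend removed, positional lists of RefSeq-matched genes only, and either block with an estimated correlation.

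Whether the replicate letters pair the samples was checked by correlating the deviations of each WT library and each mcd1-1 library from its group mean. The same letters correlated at 0.606, 0.452, 0.633 and 0.598. Different letters within A and B (0.653 and 0.490) or within C and D (0.593 and 0.643) correlated about as strongly, and letters across these sets at -0.643 to -0.448, so the correlations follow the sets and do not single out the letter. The letter was run as a block, as fixed beforehand, and blocked values stand beside a result where they change its call or a count by more than 1.5 times. The biological coefficient of variation fell to 0.161 with the block. In a principal component analysis the first component (64.8% of variance) parted the groups and the second (27.3%) parted A and B from C and D.

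The test was run on simulated data with the counts and spread of these libraries and 50 changed genes at each fold. With the pooled spread it recovered 6% of genes at 1.5-fold, 56% at 2-fold, 98% at 4-fold and 100% at 8-fold, and 3 calls (2.24% of its calls) were false. With the spread within sets it recovered 70%, 94%, 100% and 100%, and 13 calls (6.16%, above the threshold of 5%) were false. Of 40 simulated lists without a shift camera called 0, while the list with a shift was called. The genes were drawn independently, without correlation within lists or the division into A and B and C and D. Estimated correlations of the real lists reached 0.85 (histones), so the simulation does not show how often camera calls a real list by chance. Work was done in R 4.3.3 and Python 3.11.15 with pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.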

Results

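Poly(A)-selected RNA of budding yeast was sequenced from 4 wild-type (WT) and 4 mcd1-1 samples, with replicates lettered A to D in each group. MCD1, also called SCC1, encodes the kleisin subunit of cohesin, the ring complex that holds sister chromatids together, and mcd1-1 is a mutant allele of it. The strains derive from W303-1a, a haploid laboratory strain of mating type a, and grew in rich glucose medium at 31 °C for 2 generations to log phase. The comparison asks which mRNAs differ in abundance between mcd1-1 and WT cells under these conditions. The deposited table holds read counts for 6596 gene models, and the totals were 22331070, 25604790, 29761748 and 44217331 counts in WT A to D and 24880122, 24091037, 26433321 and 58506447 in mcd1-1 A to D. A count of 0 allowed up to 3 counts, or 0.051 to 0.134 CPM (counts per 1e+06 counts) depending on the library, for counting error only. Nothing in the labels states that the replicates were separate cultures, so the p-values measure the spread between these samples.

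MCD1 mRNA was 3.88-fold higher in mcd1-1 than in WT. In the same cells 131 of 139 ribosomal protein genes, 8 of 10 histone genes and 18 of 25 ergosterol genes fell. In contrast, 21 of 30 stress genes under Msn2 and Msn4, 15 of 20 DNA damage genes, 18 of 21 meiosis and sporulation genes and 222 of 440 genes near chromosome ends rose. Across the 6558 gene models tested, 2650 changed at an adjusted p under 0.05, with 1359 higher and 1291 lower in mcd1-1. A change of at least 2-fold was called for 736 genes upward and 326 downward, but for 892 and 193 under upper-quartile scaling, 1225 and 65 under library size alone, 1024 and 616 with A and B only and 724 and 88 with C and D only. In 1450 genes all 4 mcd1-1 libraries lay above all 4 WT libraries and in 1379 genes all lay below, together 43.1% of the genes, where chance gives 2.86% if all 8 libraries are exchangeable, which sets aside the division of both groups into A and B and C and D. The fold change fell with abundance across genes (Spearman rho = -0.50 with mean log2 CPM, over genes, which are not independent replicates). Among the 1000 most weakly expressed single-copy genes 502 rose and 42 fell, and among the 1000 most abundant genes 41 rose and 358 fell. With the replicate letter as a block 1927 genes rose and 1978 fell, and without mcd1-1 B 859 genes fell, 168 of them at least 2-fold. Under scaling by library size alone the median log2 fold change of all genes moved to 0.33 and 81.7% of the called genes were higher. Upper-quartile scaling moved that median to 0.13, with 65.5% of the called genes higher, whereas the median was -0.01 and the share 51.3% under the scaling used throughout. Of the genes named below, library size alone ended the calls of GPA1, HSC82, ATP20, RSM26 and MRPL10, limma-voom that of SIP18 and the block with a GC and length correction that of COX1. Among all genes picked by the rule, upper-quartile scaling ended 4 calls and leaving out 1 library ended 2 to 8, and these are not all listed.

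MCD1 itself (YDL003W, chromosome IV, 444683 to 446383, build R64) was at 80.3 ± 5.20 CPM (mean ± SD, n = 4) in WT and at 312 ± 44.6 CPM in mcd1-1. Its log2 fold change was 1.96 ± 0.15 (SE), with an adjusted p of 4.5e-05 in edgeR, and values given as a number ± another without a unit are log2 fold changes ± SE throughout. The WT libraries A to D held 80.7, 87.2, 75 and 78.1 CPM and the mcd1-1 libraries 378, 288, 286 and 295 CPM. Reads of the mutant allele count as MCD1 here, so its level checks no label. The flanking genes ATP16 and NHP10 fell by 0.43 and 0.71 on the log2 scale.

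Among the 15 genes of cohesin and its regulators, 4 rose and 11 were not called, and the count adjusted over the list alone was also 4. After MCD1 these were ECO1, the acetyltransferase that establishes cohesion (1.20 ± 0.28, adjusted p = 0.0080), SCC4, a subunit of the cohesin loader (0.80 ± 0.21, adjusted p = 0.015), and IRR1, the Scc3 subunit of the ring (0.60 ± 0.19, adjusted p = 0.031). IRR1 was not called without WT A (adjusted p = 0.079), WT B (0.084), mcd1-1 B (0.063), mcd1-1 C (0.076) or mcd1-1 D (0.071). The core subunits SMC1 (0.59 ± 0.24, adjusted p = 0.079) and SMC3 (-0.32 ± 0.28, adjusted p = 0.40) and the loader subunit SCC2 (0.30 ± 0.34, adjusted p = 0.51) were not called, though SMC1 was called without WT D (0.77, adjusted p = 0.034). With the replicate letter as a block, SMC1 (adjusted p = 0.0058) and SCC2 (0.024) were higher and SMC3 (0.039) lower, which made 6 higher and 1 lower. As a list the cohesin genes were not called (median log2 fold change 0.27, camera adjusted p = 0.144).

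**Figure D1:**
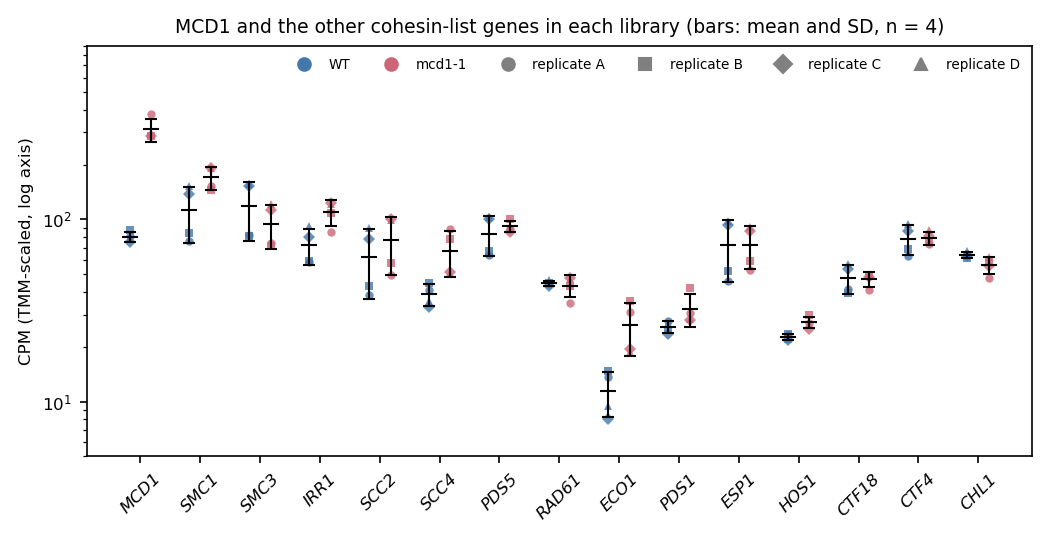
CPM (log scale) of the cohesin genes in each WT and mcd1-1 library, with points for libraries and bars for mean and SD (n = 4). MCD1 lay between 75 and 87.2 CPM in the WT libraries and between 286 and 378 CPM in the mcd1-1 libraries.

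The 13 genes of condensin and the related Smc5/6 complex included 2 higher and 1 lower gene, and 1 higher gene when adjusted over the list alone. SMC5, a core subunit of Smc5/6, rose by 0.87 ± 0.17 on the log2 scale. With the replicate letter as a block 6 rose and 1 fell, and the list was not called (median 0.18, adjusted p = 0.691). Of 34 kinetochore and spindle checkpoint genes 10 rose and 2 fell, with the same counts adjusted over the list alone, and 4 fell with the block. They included the inner kinetochore gene MIF2 (1.51 ± 0.12), the checkpoint kinase BUB1 (1.66 ± 0.24), the Aurora B kinase IPL1 (1.12 ± 0.22) and its partner SLI15 (1.04 ± 0.22). The list had a median of 0.23 and was not called (adjusted p = 0.148). Among 22 silencing and telomerase genes 4 rose and 3 fell, both over all genes and adjusted over the list alone. EST2, the telomerase reverse transcriptase, rose by 0.90 ± 0.15 and SIR1, a silencing protein of the mating-type loci, by 0.73 ± 0.17, while HMO1, a high-mobility-group protein bound at ribosomal genes, fell by 1.10 ± 0.15. The median of that list was 0.10 (adjusted p = 0.827).

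The largest rises among genes of at least 10 mean CPM were in YLR307C-A (5.48 ± 0.39), THI4 for thiamine synthesis (4.80 ± 0.55) and SPG4, a stationary-phase gene (4.68 ± 0.90). Others were the Hsp70 gene SSA3 (4.58 ± 0.37), the stress-induced hydrophilin genes GRE1 (4.55 ± 0.57) and SIP18 (3.90 ± 0.95), the minor pyruvate decarboxylase PDC6 (4.26 ± 0.21) and PHO92 (3.87 ± 0.41). The small heat-shock genes HSP26 (3.88 ± 0.47) and HSP12 (3.87 ± 0.48) went from 45.9 ± 19.4 to 676 ± 349 CPM and from 46.7 ± 11.2 to 682 ± 409 CPM (mean ± SD, n = 4). The largest falls were in the histone genes HTA2 (-2.13 ± 0.34) and HTB2 (-2.08 ± 0.20), in YOL014W (-2.06 ± 0.17) and in the daughter-cell genes DSE4 (-1.77 ± 0.40) and DSE2 (-1.67 ± 0.21). RKI1, an enzyme of the pentose phosphate pathway, fell by 1.75 ± 0.24, URA1, of pyrimidine synthesis, by 1.68 ± 0.30, and YNL303W, a model that overlaps another, by 1.66 ± 0.31. The ribosomal protein genes RPL9A and RPL8A fell by 1.68 ± 0.25 and 1.67 ± 0.23. HTA2, RPL9A and RPL8A are among the 20 named genes with a near-identical copy, and how shared reads were counted is not given in the sources used here. The same holds for overlapping models, such as YNL303W, LEU9, GAS1, ARN2, CCC2, HXT14, STE3, PAU12, PAU24, RPL28 and COX1, because the strand setting of the counting is not given.

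Of the 36 gene lists fixed in advance, 19 were called by camera with a preset correlation of 0.01, and each of these 19 calls was lost with an estimated correlation. The fry test called 24 lists, and 9 of the 35 splits of the 8 libraries into 4 and 4, the real one included, gave 19 or more called lists. The others of these 9 splits kept most libraries of a genotype together and so still carried part of the contrast. Splits that mixed the genotypes evenly called 8 to 15 lists. The counts of members that rose or fell come from the tests of single genes.

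Ribosomal protein genes fell together in mcd1-1: 131 of 139 were lower and 8 were not called, or 134 lower when adjusted over the list alone. Their median log2 fold change was -1.19, and their share of all counts was 9.69 to 13.2% in the WT libraries and 5.08 to 6.93% in the mcd1-1 libraries. Examples were RPL22B (-1.22 ± 0.12), RPL14B (-1.09 ± 0.15), RPL9B (-1.50 ± 0.19) and RPL8A (camera adjusted p = 7.6e-33 for the list, and adjusted p = 0.370 with an estimated correlation). Of 99 ribosome biogenesis genes 34 fell, 30 adjusted over the list alone and 68 with the replicate letter as a block. Among them were the processing factors UTP23 (-1.02 ± 0.14), RLP7 (-1.02 ± 0.14), NOP15 (-0.82 ± 0.12) and RRP8 (-1.07 ± 0.16). The median was -0.56 (adjusted p = 1.3e-06, and adjusted p = 0.568 with an estimated correlation). Of 39 genes for RNA polymerases I and III 14 fell and 2 rose, with the same counts adjusted over the list alone and 6 higher with the block. The subunits RPC31 (-0.81 ± 0.11), RPO26 (-1.14 ± 0.15) and RPA34 (-0.97 ± 0.15) fell, and RRN3, the initiation factor of RNA polymerase I, rose (1.69 ± 0.15). The median of that list was -0.32, but 0.0049 under library size alone (adjusted p = 0.0475, and adjusted p = 0.387 with an estimated correlation), and the call was lost without WT C (adjusted p = 0.0790), WT D (0.108) or mcd1-1 A (0.0537), under library size alone (0.0619), with a stricter filter of 10 CPM in 4 libraries (0.0933) and with the abundance trend removed (0.118).

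Ergosterol synthesis fell in 18 of 25 genes, or 19 adjusted over the list alone. ERG11, the lanosterol demethylase, went from 1626 ± 94.6 to 826 ± 177 CPM (-0.98 ± 0.19), and ERG26 (-1.43 ± 0.24), IDI1 (-0.93 ± 0.18) and ERG24 (-0.78 ± 0.15) also fell. The list median was -0.65 (adjusted p = 2.0e-05, and adjusted p = 0.527 with an estimated correlation). Amino acid biosynthesis genes under Gcn4 gave 15 lower and 2 higher of 41, or 16 and 2 adjusted over the list alone and 26 lower with the block. ORT1, the ornithine transporter, fell by 1.00 ± 0.17, SER33, of serine synthesis, by 0.91 ± 0.17 and LEU9, of leucine synthesis, by 1.43 ± 0.29, while LYS1, of lysine synthesis, rose by 0.94 ± 0.14. Their median was -0.49 (adjusted p = 0.0060, and adjusted p = 0.718 with an estimated correlation), and the call was also lost with fry (0.128) and with the abundance trend removed (0.792). The phosphate regulon gave 7 lower and 2 higher of 17, or 10 and 2 adjusted over the list alone and 12 lower with the block. It included SPL2 (-1.27 ± 0.21), PHM6 (-1.03 ± 0.16), the polyphosphate synthase subunit VTC1 (-0.97 ± 0.20) and PHO86 (-0.76 ± 0.16). The median was -0.76 (adjusted p = 0.0106, and adjusted p = 0.387 with an estimated correlation), and the call was lost with the trend removed (0.287).

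In glycolysis and fermentation 11 of 23 genes fell and 3 rose, or 12 and 3 adjusted over the list alone. TDH2, a glyceraldehyde phosphate dehydrogenase, fell by 1.01 ± 0.19 and HXK2, the main hexokinase in glucose, by 0.96 ± 0.18, while PDC6 rose from 3.65 ± 0.52 to 69.6 ± 17.5 CPM and PDC5 rose by 1.38 ± 0.22. With a median of -0.68 the list was not called (adjusted p = 0.102). Sulfur and methionine genes went both ways, 6 up and 6 down of 25 and the same adjusted over the list alone. The sulfate permease SUL1 rose (1.65 ± 0.21), whereas MET22 (-1.23 ± 0.21), MET14 (-1.16 ± 0.22) and SAM2 (-0.76 ± 0.14) fell (median 0.24, adjusted p = 0.931). Of 17 purine synthesis genes 3 rose and 2 fell, with 5 lower under the block. Adjusted over the list alone edgeR called 0, where 3 higher and 3 lower had an unadjusted p under 0.05 and DESeq2 called 3 and 4 and limma-voom 2 and 3 over all genes (median -0.13, but 0.20 under library size alone, adjusted p = 0.587). Of 25 genes of the iron regulon 10 rose and 4 fell, or 11 and 4 adjusted over the list alone. The cell-wall mannoproteins FIT1 (1.86 ± 0.28) and FIT2 (1.43 ± 0.18), the siderophore transporter ARN2 (1.19 ± 0.14) and the copper transporter CCC2 (0.90 ± 0.10) were among the rises (median 0.38, adjusted p = 0.0969, list not called; called at 0.0230 with the abundance trend removed). Nitrogen catabolite genes gave 12 higher and 2 lower of 23, or 12 and 5 adjusted over the list alone and also with the block. DUR3 (1.79 ± 0.19), DAL1 (1.43 ± 0.14), PUT1 (1.43 ± 0.22) and GDH2 (1.01 ± 0.14) rose (median 0.57, adjusted p = 0.0546, list not called). Without mcd1-1 C or D that list was called, at adjusted p = 0.0255 and 0.0436, and also with the abundance trend removed (0.0030).

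Stress genes under Msn2 and Msn4 rose in 21 of 30 cases, also when adjusted over the list alone. Besides HSP26 these included MOH1 (2.24 ± 0.23), the glycogen debranching enzyme GDB1 (1.98 ± 0.20) and UGX2 (2.03 ± 0.24). The list median was 1.38 (adjusted p = 1.45e-08, and adjusted p = 0.387 with an estimated correlation). Heat-shock chaperone genes under Hsf1 gave 4 higher and 3 lower of 24, with the same counts adjusted over the list alone. SSA3 went from 31.6 ± 5.74 to 754 ± 380 CPM, SSA4 from 150 ± 77.7 to 1248 ± 728 CPM (3.06 ± 0.53) and SSE2 rose by 1.77 ± 0.24, while the Hsp90 gene HSC82 fell by 0.71 ± 0.15. That list was not called (median 0.32, adjusted p = 0.199), but with the replicate letter as a block 11 rose, 5 fell and the adjusted p was 0.0488 (adjusted p = 0.579 with that block and an estimated correlation). With the abundance trend removed the Hsf1 list was called higher (adjusted p = 5.4e-07). DNA damage response genes rose in 15 of 20 cases, and adjusted over the list alone 15 rose and 1 fell. HUG1, a target of the Mec1 checkpoint, went from 7.99 ± 0.77 to 30.6 ± 2.53 CPM (1.93 ± 0.14), PLM2 rose by 1.31 ± 0.14, and the near-identical pair DDI2 (2.07 ± 0.14) and DDI3 (2.08 ± 0.14) rose together. The median of the damage list was 0.92 (adjusted p = 1.0e-06, and adjusted p = 0.136 with an estimated correlation), with 3 lower genes under the block. In the proteasome list the 1 gene called of 38, also adjusted over the list alone, was RPN4, the transcription factor of proteasome genes, from 81.2 ± 12.0 to 346 ± 123 CPM (2.09 ± 0.26). With the block 4 rose and 1 fell. The proteasome list was not called (adjusted p = 0.753), with a median of -0.04, a mean of 0.0031 and a test pointing down, and its median was positive under upper-quartile scaling (0.09) and library size alone (0.30). With the trend removed it was called higher (adjusted p = 0.0113).

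Histone genes fell in 8 of 10 cases, 9 adjusted over the list alone. HTB2 went from 342 ± 47.7 to 81.1 ± 18.5 CPM, and HTA2, HHF2 (-1.30 ± 0.18) and HTB1 (-0.96 ± 0.16) also fell. Their median was -1.07 (adjusted p = 1.2e-05, and adjusted p = 0.387 with an estimated correlation). Genes of mitotic exit and early G1, many of them expressed in daughter cells, gave 10 lower and 2 higher of 23, with the same counts adjusted over the list alone. The cell-separation genes DSE1 (-1.57 ± 0.17), DSE2, EGT2 (-1.59 ± 0.23) and SCW11 (-1.31 ± 0.20) fell. The median of this list was -0.16, but 0.17 under library size alone (adjusted p = 0.0106, and adjusted p = 0.568 with an estimated correlation), and the call was lost with the abundance trend removed (0.422). The CLB2 cluster of G2 and mitosis gave 9 higher and 1 lower of 22, also adjusted over the list alone, and 14 higher with the block. CDC20, the activator of the anaphase-promoting complex, rose by 0.88 ± 0.20, HST3, a histone deacetylase, by 1.17 ± 0.20, WSC4 by 0.93 ± 0.13 and PMA2 by 1.81 ± 0.34. The median was 0.51 (adjusted p = 0.0127, and adjusted p = 0.607 with an estimated correlation). The G1/S targets, transcribed at the start of the cycle under SBF and MBF, gave 6 higher and 6 lower of 35, also adjusted over the list alone, and 11 lower with the block. CDC45 (0.76 ± 0.12), DPB2 (0.59 ± 0.12) and GIC1 (0.88 ± 0.18) rose and MNN1 fell (-1.30 ± 0.18). The G1/S median was -0.06, but 0.07 under upper-quartile scaling and 0.28 under library size alone, and the list was not called (adjusted p = 0.698).

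Several groups that are silent or weakly expressed in these haploid cells in glucose rose from low levels, such as meiosis and sporulation, subtelomeric and galactose genes. Hexose transporter genes, which as a list had a higher WT level, are given beside them. The median gain of the 1000 weakest single-copy genes was 7.34 CPM per kb, from 16.5 to 26.0 CPM per kb in group medians, and each gain below stands against it. For a list the gain is a median over all tested members, whether or not they rose. Genes of meiosis and sporulation, drawn in the figure as early meiosis genes, rose in 18 of 21 cases, also adjusted over the list alone. Their median gain was 8.53 CPM per kb, and 5 of the 18 gained more than 2 times the 7.34. The list is not limited to early genes, and SPS1, SMK1 and SSP1 in it also belong to the ascospore wall term in the closing section. REC104 (2.14 ± 0.20), SPS1 (1.89 ± 0.20) and SPO13 (1.93 ± 0.23) were examples (median 1.29, adjusted p = 7.5e-09, and adjusted p = 0.145 with an estimated correlation). Subtelomeric families such as the PAU genes rose in 31 of 44 cases, 34 adjusted over the list alone, with a median gain of 12.7 CPM per kb, and 16 of the 31 gained more than 2 times the 7.34. PAU23 went from 7.95 ± 0.96 to 31.0 ± 4.87 CPM, and PAU3 (2.96 ± 0.26), PAU24 (3.29 ± 0.25) and PAU12 (3.12 ± 0.27) rose too, all with near-identical copies. The list median was 1.51 (adjusted p = 6.0e-15, and adjusted p = 0.0549 with an estimated correlation). Hexose transporter genes gave 10 higher and 1 lower of 18, or 11 and 1 adjusted over the list alone. Their median gain was 11 CPM per kb, and 4 of the 10 gained more than 2 times the 7.34. The WT median of this list lay above the 16.5 CPM per kb of the weak genes in WT. HXT10 (2.71 ± 0.18), HXT9 (2.22 ± 0.12), HXT14 (2.04 ± 0.22) and the glucose sensor SNF3 (1.10 ± 0.12) rose (median 0.75, adjusted p = 1.9e-05, and adjusted p = 0.0549 with an estimated correlation). Galactose genes rose in 5 of 7 cases, 6 adjusted over the list alone, with a median gain of 6.85 CPM per kb, and 0 of the 5 gained more than 2 times the 7.34. GAL1, the galactokinase, went from 7.07 ± 2.02 to 20.5 ± 1.26 CPM, and GAL2 (1.36 ± 0.17), GAL3 (0.90 ± 0.14) and GAL7 (1.46 ± 0.25) also rose (median 0.90, adjusted p = 0.0029, and adjusted p = 0.387 with an estimated correlation).

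Pheromone response genes gave 9 higher and 3 lower of 22, also adjusted over the list alone, with a median gain of 7.80 CPM per kb. Of the 9, 2 gained more than 2 times the 7.34 CPM per kb of weak genes. FIG1 (2.46 ± 0.21) and PRM1 (1.55 ± 0.16) rose and PRM4 fell (-0.75 ± 0.13). Their median was 0.49 (adjusted p = 0.0331, and adjusted p = 0.370 with an estimated correlation), and the call was lost with the stricter filter (0.0885) and with the abundance trend removed (0.130). Of the 4 alpha-specific genes, whose activator mating type a cells lack, 3 rose and all 4 were higher adjusted over the list alone, with a median gain of 9.73 CPM per kb. Among the 3 that rose, 1 gained more than 2 times the 7.34. MF(ALPHA)1 went from 0.718 ± 0.206 to 5.38 ± 1.19 CPM, SAG1 from 28.5 ± 6.84 to 84.6 ± 13.9 CPM and STE3, whose model overlaps another, from 5.21 ± 0.61 to 19.5 ± 3.49 CPM, while MF(ALPHA)2 was not called (0.55 ± 0.20, adjusted p = 0.052; 0.016 with the block, 0.0498 without WT A and 0.024 without mcd1-1 C). The list median was 1.74 (adjusted p = 0.00017, and adjusted p = 0.145 with an estimated correlation), and the call was lost with the trend removed (0.0710). Of 7 a-specific genes the agglutinin subunit AGA2 rose (0.55 ± 0.15), the 1 call over all genes and adjusted over the list alone, and the receptor STE2 was at 367 ± 37.7 CPM in WT and 277 ± 75.8 CPM in mcd1-1 (adjusted p = 0.148). With the block 3 of these rose and 3 fell (median -0.41, adjusted p = 0.800 for the list). Of 12 haploid-specific genes 4 fell, also adjusted over the list alone, with 2 higher under the block. HO, the mating-type switching endonuclease, fell by 1.64 ± 0.15, the G protein subunits STE4 and GPA1 by 1.00 ± 0.14 and 0.57 ± 0.13 and RME1 by 0.80 ± 0.13. Their median was -0.06, but 0.07 under upper-quartile scaling and 0.28 under library size alone, and the list was not called (adjusted p = 0.0969). Of 11 strain marker genes URA3, from 320 ± 40 to 124 ± 18.8 CPM, HO and RPL28 (-1.16 ± 0.23) fell, 3 also adjusted over the list alone, with 2 higher under the block. The others, including LEU2 (0.42 ± 0.18; called without mcd1-1 B at adjusted p = 0.030), HIS3 (-0.01 ± 0.21) and LYS2 (-0.02 ± 0.48), were not called. The marker median was -0.15, but 0.0051 under upper-quartile scaling and 0.19 under library size alone (adjusted p = 0.0827, list not called). The full genotypes are not given in the sources used here, so whether the values of URA3, HO and RPL28 reflect differences of markers or strains was not tested. RPL28 is also a member of the ribosomal protein list, whose median was -1.19, so its fall does not stand apart from that list. HMRA1 was at 57.2 ± 20.2 and 58.0 ± 12.0 CPM and MATALPHA1 at 1.51 ± 0.99 and 3.08 ± 1.35 CPM in WT and mcd1-1 (adjusted p = 0.96 and 0.137; 0.0067 for MATALPHA1 with the block).

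Cell wall integrity genes gave 3 higher and 5 lower of 22, also adjusted over the list alone. GSC2, a glucan synthase subunit, rose by 1.58 ± 0.16 and PIR3 by 2.71 ± 0.34, while CWP1 fell by 0.85 ± 0.15 and GAS1 by 1.17 ± 0.23. The list was not called (adjusted p = 0.931), with a median of 0.02 and a mean of 0.07 but a test pointing down, and its median was slightly negative under RLE scaling (-0.00084) and under TMM without ribosomal protein genes (-0.0066). With the trend removed that list was called higher (adjusted p = 0.0030).

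Transcripts of the mitochondrial genome, which lack stable poly(A) tails in yeast, made up 0.0180 to 0.0704% of counts in the WT libraries and 0.132 to 0.477% in the mcd1-1 libraries, with the highest share in mcd1-1 A. Of 6 mitochondrially encoded genes 4 rose, and 6 adjusted over the list alone, with a median gain of 11 CPM per kb. COX1, of cytochrome c oxidase, went from 114 ± 72.2 to 576 ± 405 CPM (2.34 ± 0.54), and ATP6, of the ATP synthase, from 3.55 ± 2.16 to 18.3 ± 9.14 CPM (2.34 ± 0.48). The list median was 2.01 (adjusted p = 0.0331, and adjusted p = 0.568 with an estimated correlation), and the call was lost with the replicate letter as a block (0.118), without mcd1-1 A (0.0503), under library size alone (0.0822), with the stricter filter (0.0705) and with the abundance trend removed (0.502). Nuclear genes for the mitochondrial ribosome fell in 14 of 71 cases and in 49 with the block, with RSM26 (-0.88 ± 0.22) and MRPL10 (-0.86 ± 0.22) as examples. Adjusted over the list alone edgeR called 0 of them, where 24 were lower at an unadjusted p under 0.05, and over all genes DESeq2 called 21 lower and limma-voom 13. Their median was -0.42 (adjusted p = 0.0012, and adjusted p = 0.756 with an estimated correlation), and the call was lost with fry (0.226). In the TCA cycle and respiratory chain 10 of 47 genes fell and 1 rose, and adjusted over the list alone 1 fell and 1 rose. CYC7, the minor form of cytochrome c, rose by 1.40 ± 0.19, and ATP20, of the ATP synthase, fell by 0.70 ± 0.16. With the block 2 rose. The list median was -0.23, but 0.11 under library size alone (adjusted p = 0.0793, not called), and the list was called without WT C (adjusted p = 0.0325), WT D (0.0167) or mcd1-1 A (0.0228).

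**Figure D2:**
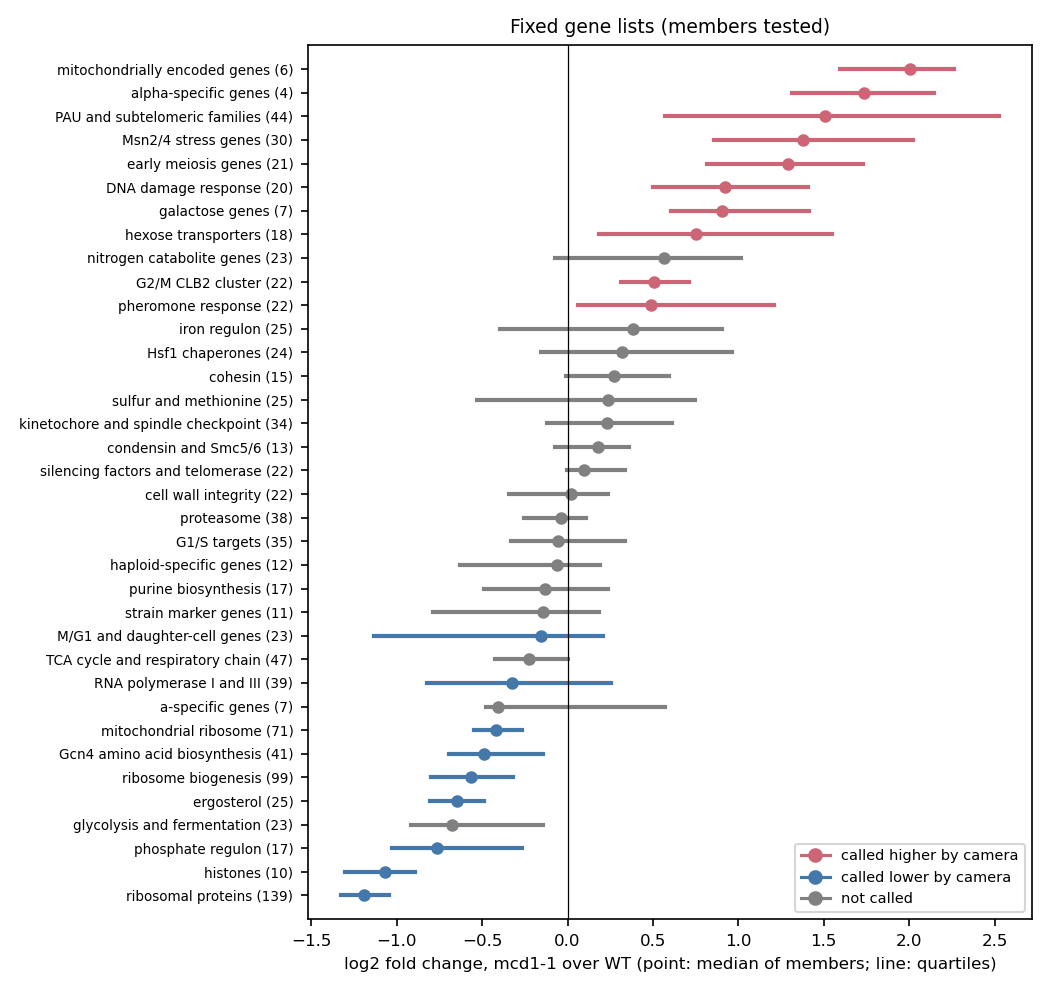
Median log2 fold change, mcd1-1 over WT, of each of the 36 fixed gene lists (points, with lines between the quartiles of members, red and blue for lists called higher and lower by camera). Ribosomal proteins had a median of -1.19 and Msn2/4 stress genes of 1.38, while RNA polymerase I and III, the daughter-cell genes, the TCA cycle and purine synthesis turn positive under library size alone and G1/S targets, haploid-specific genes, strain markers, the proteasome and cell wall integrity flip under 2 scalings each. The median of all genes was 0.33 under library size alone and 0.13 under upper-quartile scaling.

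Genes near chromosome ends rose. Of 440 tested genes within 30 kb of an end 222 rose and 24 fell, or 235 and 28 adjusted over the list alone and 40 lower with the replicate letter as a block, with a median log2 fold change of 0.77. Examples were DSF1, a mannitol dehydrogenase homologue, from 7.04 ± 0.70 to 86.4 ± 20.5 CPM (3.62 ± 0.20), HSP32 (3.46 ± 0.20), ERR1, an enolase-related gene (3.06 ± 0.18), and HXT9, all with near-identical copies. The call held with an estimated correlation (camera adjusted p = 1.0e-16, and adjusted p = 0.0014 with an estimated correlation). In bins of distance the median was 0.79 within 5 kb, 1.45 from 5 to 10 kb, 0.89 from 10 to 20 kb, 0.26 from 20 to 30 kb and -0.0021 from 30 to 50 kb. Among genes with no near-identical copy the medians of the first 4 bins were 0.35 (8 genes), 1.41 (23 genes), 0.51 and 0.17. Genes within 15 kb of a centromere gave 81 lower and 35 higher of 256, or 82 and 36 adjusted over the list alone, with a median of -0.22. Under library size alone that median was 0.12, where the median of all genes was 0.33, and the list was still called lower (camera adjusted p = 0.010). Within this distance LSO1 (5.50 ± 0.39) and MCD1 rose and HTB2 and the methyltransferase gene EFM5 (-1.28 ± 0.12) fell. Within 5 kb of a centromere 36 of 90 genes fell and 6 rose, at a median of -0.37, from 5 to 10 kb 29 fell and 9 rose, and from 10 to 15 kb the median was -0.01. The centromere list was called (adjusted p = 0.0057, and adjusted p = 0.187 with an estimated correlation). The 3072 genes with a convergent neighbour gave 546 higher and 693 lower, also adjusted over the list alone, and the list was not called (adjusted p = 0.0835), with a median of -0.08 and a mean of 0.02, and with a positive median under upper-quartile scaling (0.05) and library size alone (0.26). PDC6 and RIM4, a regulator of meiosis (1.82 ± 0.11), were among its rises.

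**Figure D3:**
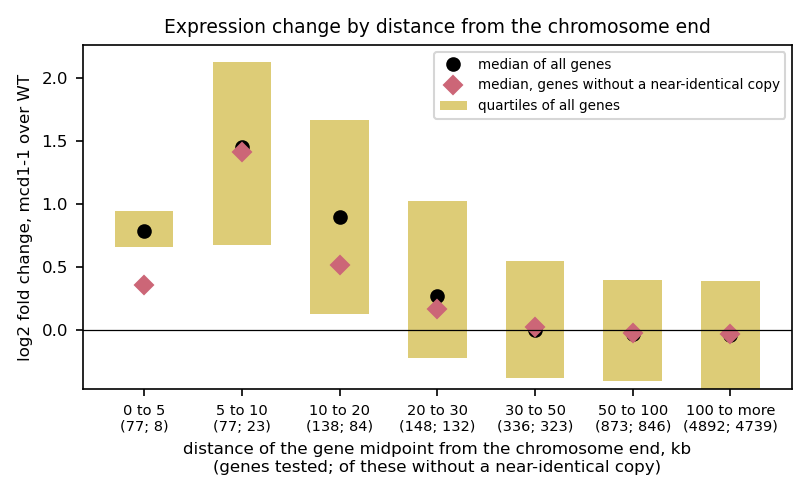
Log2 fold change, mcd1-1 over WT, against distance to the nearest chromosome end in kb, in bins, with circles for medians of all genes, bars for their quartiles and diamonds for medians of genes without a near-identical copy. The bin from 5 to 10 kb has a median of 1.45, and the 3 bins beyond 30 kb have medians of -0.0021, -0.03 and -0.04.

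Whole chromosomes did not pass the test in the full comparison. For the 16 nuclear chromosomes camera called 0, where chromosomes VI (median 0.21, unadjusted p = 0.0090, adjusted p = 0.144) and XII (0.18, unadjusted p = 0.020, adjusted p = 0.162) had the only unadjusted p-values under 0.05, and fry, which asks whether genes move one way on balance, called 11. With the replicate letter as a block chromosome VI was called (adjusted p = 0.0456), but not with that block and an estimated correlation (adjusted p = 0.157). Under 2 settings chosen after the data were seen, camera called VI and XII higher with C and D only (adjusted p = 0.0497 each). It called XII higher with the abundance trend removed (adjusted p = 0.0167). The differences between the group means of each chromosome's library median lay between -0.09 and 0.19. An exact 2-sided permutation test of them over the 70 assignments gave its smallest possible p, 0.0286, for 8 chromosomes, 0.0571 after Benjamini-Hochberg adjustment over 16. For chromosomes II, IV, V, VII, XI, XIII, XV and XVI the mean was positive while the median was negative and the test pointed down, and for X the median was negative while the mean was positive and the test pointed up, and all 9 medians were positive under upper-quartile scaling and library size alone.

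Libraries A and B of both groups stood apart from C and D, so the contrast was also made within each of these sets, a division chosen after the data were seen. The test called 4451 genes in A and B and 4985 in C and D. The log2 fold changes of the sets correlated at r = 0.84 (rho = 0.81) across 6557 genes, which are not independent replicates. In both sets 1799 genes were higher and 1690 lower, against 882 and 804 for independent lists, and 205 were called with opposite signs. MCD1 was higher by 1.99 in A and B and by 1.96 in C and D (adjusted p = 0.79 for the difference). The change was larger in A and B for 77.8% of the called genes, with a median absolute log2 fold change of 1.06 against 0.70, and the difference between the sets was called for 2408 genes. Ribosomal protein genes had medians of -1.50 in A and B and -0.82 in C and D, Msn2/4 stress genes of 1.51 and 1.18 and genes near chromosome ends of 1.00 and 0.64. Camera called 18 lists in A and B, without the daughter-cell genes (adjusted p = 0.135), the pheromone response (0.112) and RNA polymerases I and III (0.135), and 20 lists in C and D, without the mitochondrially encoded genes (median 0.69, adjusted p = 0.615).

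**Figure D4:**
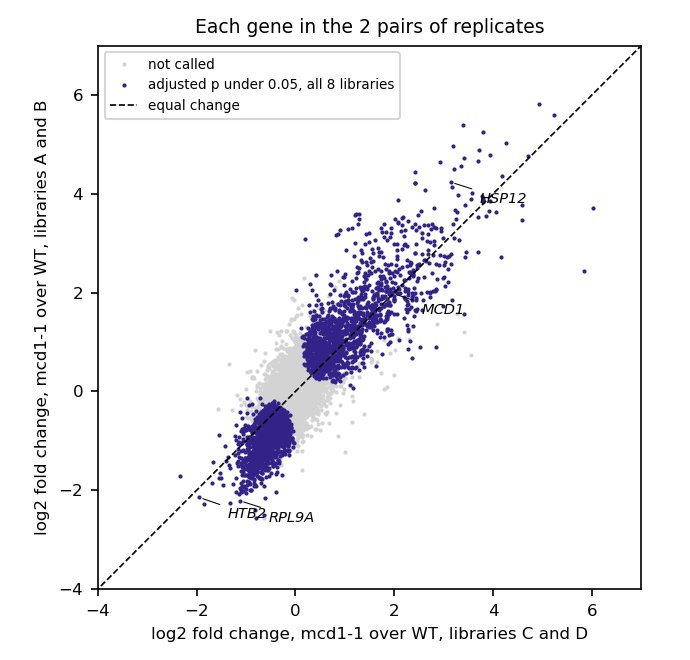
Log2 fold change, mcd1-1 over WT, from libraries A and B against that from C and D, with 1 point per gene. The points follow each other at r = 0.84, with larger changes in A and B for 77.8% of the called genes.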

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

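The tests of an even background, of genomic DNA, of abundance and of an even background at chromosome ends, of shared reads within 10 kb of an end, of the G1/S genes and of the MCD1 locus were chosen only after the result was seen, as was the comparison of libraries A and B with C and D, while those of depth, of shared reads at all ends, of the abundance of MCD1 and of the splits were fixed before.

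Several libraries stood far from the others of their group. The total of mcd1-1 D was 58.5 in units of 1e+06 counts, against 26.4 for the nearest library of its group. The mitochondrially encoded share of mcd1-1 A was 0.477%, against 0.166% for the nearest. MCD1 was at 378 CPM in mcd1-1 A, against 295 CPM for the nearest. The median deviation of the kinetochore list was -0.22 in WT C, against -0.11 for the nearest, and that of the DNA damage list was 0.78 in mcd1-1 B, against 0.40 for the nearest. Of 150 groups of 4 values tested, 5 exceeded Dixon's critical value for 4 values, where chance gives 7.5. The fold change between mcd1-1 and WT differed between libraries A and B and libraries C and D for 2408 genes, by a test of the difference itself. That test measures the difference against the spread of libraries within each set. It cannot tell a differing effect of mcd1-1 from any other difference between these pairs of libraries.

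Of the 1000 weakest single-copy genes 502 rose and 42 fell in mcd1-1, and of the 1000 most abundant 41 rose and 358 fell. The tables argue against a difference in depth, because the trend was about as strong in replicates A to C alone (rho = -0.49, against -0.50 in all libraries), where the summed counts of the groups differed by a ratio of 0.970. For genomic DNA the loci of the mitochondrial genome were mixed. With overlapping models counted once, 3 of 8 gained less than 0.5 times the median of 7.34 CPM per kb of the weak nuclear genes (COB 0.411, COX2 3.17 and COX3 1.21). Even the whole mcd1-1 levels of COB (0.932), COX2 (4.10) and COX3 (1.85 CPM per kb) lay below 7.34. This argues against genomic DNA of that depth at these 3 loci. Others gained far more (OLI1 135, SCEI 44.7, COX1 34.5 and ATP6 18.9), and there genomic DNA cannot be told apart from a change of expression. An even background of reads over the nuclear genome may contribute, since of the 122 weak genes that lay below 3.67 CPM per kb in WT 4 (3.28%) stayed below it in mcd1-1. A broad rise of weak transcripts could pass that test too. The gains of these 122 genes ran from 2.77 (10th percentile) to 13.9 CPM per kb (90th percentile), where an even background adds the same per kb to each. Of the 1359 higher genes 597 gained at most 2 times the 7.34 CPM per kb of the weak genes. More than that was gained by 0 of 4 higher silencing genes, 0 of 2 condensin, 0 of 6 G1/S and 3 of 10 kinetochore genes. The same held for 3 of 4 higher cohesin genes, 12 of 15 DNA damage genes and 21 of 21 Msn2/4 genes. First forms of both tests were replaced, since that of the background, over all 1000 weak genes, could not come out against it (12.2% of them lay below that level in WT), and that of genomic DNA counted 6 of 17 models as low, of which 4 overlap at the COB locus, and a change of weak transcripts with the genotype stays open as untested.

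Genes near chromosome ends rose in mcd1-1. The trend with mean abundance alone is argued against, because their median of 0.77 lay at percentile 100 of 10000 abundance-matched random lists, whose highest median was 0.36. The single-copy genes near an end also lay at percentile 100 of lists matched on CPM per kb (0.36, highest list median 0.32). Both matchings used the mean of WT and mcd1-1, which includes the rise itself. The fold change fell more steeply with the WT level (rho = -0.63) than with that mean (rho = -0.50). Lists matched on the WT level were not drawn, so an even background is not decided at the ends. The 31 single-copy genes within 10 kb had a median of 1.19, but this rests on those from 5 to 10 kb (23 genes, median 1.41). There, reads shared between near-identical copies are argued against. Within 5 kb the 8 single-copy genes had a median of 0.35, against 0.79 for all genes, which does not decide. Shared reads also cannot be told apart from a change of expression over the whole 30 kb, where single-copy genes had a median of 0.36 and genes with a copy 0.94. A biological difference between the genotypes at the ends is consistent with these values and stays a hypothesis.

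MCD1 mRNA rose in mcd1-1. More cells in the stage that transcribes the G1/S genes is argued against, because the median of that list was -0.058 with a median absolute deviation of 0.35. A change of the whole locus is argued against as well, since the larger fold change of its neighbours was -0.43, and so is the abundance trend, since MCD1 lay at percentile 98 among the 400 genes nearest in mean abundance. That mean covers both groups and so includes the rise of MCD1 itself, and genes nearest in WT level were not compared. An effect of the mcd1-1 allele on the level of its own mRNA may remain, and neither its transcription nor its decay was tested.

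Among the 35 splits of the 8 libraries into 4 and 4, 1 gave as many changed genes as the real split, the real one itself (2650, highest other 1381), and likewise 1 for genes changed at least 2-fold (1062, highest other 358), so chance can be excluded for both only if the 8 libraries are taken as exchangeable. The split with 1381 genes set A and B against C and D and so points to a structure of the samples. With that set as a block the real contrast called 4448 genes. The 8 splits that part all 4 letters, as the real one does, are too few for a share under 0.05, and the other 7 called 0 genes by edgeR, with 0 to 373 genes at an unadjusted p under 0.05. For lists chance was not excluded, and these splits cannot decide on it. As many gene lists (19, highest other 20) were called in 9 splits and as many positional lists (2, highest other 3) in 13. The others of these splits kept 3 libraries of a genotype together and so still carried part of the contrast. Splits that mixed the genotypes evenly called 8 to 15 gene lists and 0 or 1 positional lists. For chromosomes the real count was 0, which all 35 splits reach whatever the data (highest other 1), so their number decides nothing.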

How the results depend on the processing

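The settings that use libraries A and B or C and D, the GC and length correction, the removal of the abundance trend and either block with an estimated correlation were chosen only after the data were seen, and the others were planned. MCD1 was higher and past the threshold in each of 22 alternative fits, with a log2 fold change of 1.90 (without mcd1-1 A) to 2.29 (library size alone). All 2650 called genes kept their sign in each fit that tested them, apart from 7 under library size alone, 3 under the replicate block with a GC and length correction and 1 not tested in A and B alone. The number of genes changed was 2066 to 2539 with 1 library left out, 4448 with sets A/B and C/D as a block, 4451 with A and B only, 4985 with C and D only and 4076 with the replicate block and a GC and length correction. At least 2-fold changes numbered 855 to 1155 with 1 library left out and 1640 with A and B only. The common coefficient of variation was 0.0557 to 0.146 in the fits by set and in that with the block and correction, against 0.253 in the full comparison and 0.249 to 0.258 with 1 library left out, and the cause was not tested.

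Called gene lists numbered 18 to 20 with 1 library left out, and camera called 0 with an estimated correlation, with the replicate block and an estimated correlation, and with the set block and an estimated correlation, where 5, 3 and 6 lists had an unadjusted p under 0.05, while fry called 24 and camera on voom values 22. Positional lists called numbered 2 with each library left out and fell from 2 to 1 with an estimated correlation, also under the replicate block or the set block, and with 30 kb around centromeres, and rose to 3 with A and B only, where genes with a convergent neighbour were called lower (adjusted p = 0.0423). Chromosomes called by camera numbered 0 with each library left out, where 2 had an unadjusted p under 0.05, and rose from 0 to 11 with fry, 1 with the replicate block (VI), 2 with C and D only (VI and XII) and 1 with the abundance trend removed (XII). The cause was not tested.

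Removing the abundance trend turned the proteasome (adjusted p = 0.0113, range 0.0113 to 0.995) and cell wall integrity (0.0030, range 0.0030 to 0.983) to higher and ended 7 calls, those of the daughter-cell genes, the pheromone response, alpha-specific genes, RNA polymerases I and III, Gcn4 targets, the phosphate regulon and mitochondrially encoded genes, and added as higher the Hsf1 chaperones (5.4e-07), nitrogen catabolite genes (0.0030) and the iron regulon (0.0230). Chromosomes II (0.0488, range 0.0488 to 1.00) and XI (0.0337, range 0.0337 to 1.00) pointed up in fry. The gene PDS5 was at -0.15 with C and D only (adjusted p = 0.020, range 0.0024 to 0.92), the gene ESP1 at -0.25 with the replicate block and a GC and length correction (0.023, range 0.023 to 0.99) and the gene CAN1 at 0.47 with A and B only (0.0027, range 6.2e-05 to 0.99), each opposite to its sign in the full comparison, and the cause was not tested. Fry ended the calls of Gcn4 targets (0.128) and the mitochondrial ribosome (0.226) and added 7, and library size alone ended those of RNA polymerases I and III (0.0619) and mitochondrially encoded genes (0.0822) and added that of glycolysis (0.0478). Of 189 named genes besides MCD1, library size alone ended 13 calls and added 11. The replicate block ended the call of OLI1 and added 17, those of SMC1, SMC3, SCC2, MF(ALPHA)2, MATALPHA1, HMLALPHA1, ADE2, TRP1, BAR1, STE6, STE18, MFA1, MFA2, ASG7, MMS21, RPN14 and UMP1. Among gene lists, positional lists and chromosomes that block gained the Hsf1 chaperones and chromosome VI, lost the mitochondrially encoded genes and changed no other call. With sets A/B and C/D as a block, 22 named genes and 2 gene lists gained a call and 1 gene list lost its call. Calls of positional lists and chromosomes stayed the same, with 918 higher and 1172 lower genes among those with a convergent neighbour. The stricter filter ended 3 calls of lists, those of the pheromone response (0.0885), RNA polymerases I and III (0.0933) and mitochondrially encoded genes (0.0705), added those of the iron regulon (0.0409) and nitrogen catabolite genes (0.0227), and left the alpha-specific list with fewer than 3 members and so no value. Of simulated 1.5-fold changes 6% were recovered at the pooled spread and 70% at the spread within sets, and recovery by depth was not tested.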

Other observations

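The terms below were picked, and their members named, after the values of 577 Gene Ontology terms had been seen, so all of their tests are exploratory. Camera called 72 of the 577 terms with the preset correlation, 85 with the replicate letter as a block, and each of the 72 calls was lost with an estimated correlation, where the lowest adjusted p was 0.340. Thiamine biosynthesis rose in 10 of 11 genes, with THI4 (4.80), THI5 (2.89), THI12 (2.21), SNZ3 (1.72) and THI13 (1.53) among them (THI5, THI12 and THI13 belong to a family of near-identical genes), a median log2 fold change of 1.64 and a median gain of 19.4 CPM per kb (adjusted p = 5.8e-08, and adjusted p = 0.862 with an estimated correlation). Ascospore wall genes gave 30 higher and 2 lower of 48, such as CDA1 (2.40), LDS1 (2.38), DIT1 (2.02) and LOH1 (2.00), with a median of 0.78 and a median gain of 7.57 CPM per kb, close to the 7.34 CPM per kb of weak genes (adjusted p = 3.4e-09, and adjusted p = 0.732 with an estimated correlation). This term shares SPS1, SMK1 and SSP1 with the fixed list of meiosis and sporulation genes, so the 2 are not separate observations. Genes of the peroxisomal matrix, where fatty acids are oxidised, rose in 8 of 12 cases, with POT1 (3.52), MLS1 (1.85), POX1 (1.40) and CTA1 (1.13), a median of 0.81 and a median gain of 11.4 CPM per kb (adjusted p = 0.0136, and adjusted p = 0.883 with an estimated correlation).

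In 4 single terms more genes fell than rose. COPII vesicle genes fell in 16 of 22 cases, such as ERV14 (-1.04) and ERP1 (-1.12), with a median of -0.76 (adjusted p = 8.4e-04, and adjusted p = 0.907 with an estimated correlation). N-linked glycosylation gave 18 lower and 1 higher (MNN4, 1.00) of 30, with MNN10 (-0.88), GNT1 (-1.12) and WBP1 (-0.85) and a median of -0.48 (adjusted p = 4.6e-04, and adjusted p = 0.862 with an estimated correlation). Import into the mitochondrial matrix gave 14 lower and 1 higher (AFG3, 0.92) of 23, with PAM18 (-0.82), TIM50 (-0.95) and MGE1 (-1.20) and a median of -0.63 (adjusted p = 6.4e-04, and adjusted p = 0.862 with an estimated correlation). Translation initiation factors fell in 15 of 25 cases, with TIF1 (-1.19), TIF2 (-1.26) and TIF11 (-0.94) and a median of -0.64 (adjusted p = 8.4e-04, and adjusted p = 0.862 with an estimated correlation), and the call was lost with the abundance trend removed (0.190).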
